A study of Mus musculus with 8 samples.

How the data were processed

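Lineage-negative cells, a fraction enriched for blood stem and progenitor cells, were taken from the livers of C57BL/6 mouse embryos at day 14.5 and cultured. Per the labels' protocols they received OHT at 100 nM or ethanol, the solvent control, for 24 h. OHT is read here as 4-hydroxytamoxifen, an estrogen receptor ligand used to switch on recombinases fused to that receptor. The labels name no genotype. Each group had 4 samples, and each sample was hybridised as Cy3-labelled RNA to 1 single-colour Illumina bead array. The labels do not say whether the samples of a group came from separate livers or cultures, so p-values measure the spread between these samples, which may be technical.

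The deposited table of non-normalized values holds, per its header, an intensity on the linear scale and a detection value for each of 25695 rows on each of the 8 arrays. The detection p-value was taken as 1 minus the deposited value, because within each array the deposited value rose with intensity. The authors' value table was found to hold log2 intensities that match quantile normalization of the deposited intensities, taken to log2 with no background correction, within 0.00939 on every row and array. The match was found from the values, and the array medians of that table lay between 7.564 and 7.565. The submitters' processing notes name limma without a version. Ranks within an array were identical in both tables (Spearman correlation of 1 on each array), so both attach the values to the row IDs in the same way. No slide or scan date is named in the files used here.

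Row IDs were looked up in the platform annotation supplied with the value table. Of the 25695 rows, 23976 carried 1 gene symbol. The other 1719 carried no single symbol, and rows with none and with several were not counted apart. Before any gene was named, the brightness of the rows was compared with the genes that their IDs stand for, using the mean log2 intensity over the 8 arrays expressed as a percentile of all rows. Rows were grouped by 4 gene families and by 31 gene lists fixed before the data were examined, and each median was set against 10000 random row sets of the same size. Means of the receptor and ribosomal families were compared by a two-sided permutation test with 100000 resamples. Brightness was also correlated between neighbouring rows in the order of the file and between the 2 rows of symbols that have 2. The change with OHT was correlated between neighbouring kept rows in the same way.

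The plan fixed before the data were examined called for Prmt5, a named set of genes and the gene lists to be reported. The rule for named genes took the 10 largest increases and 10 largest decreases among genes past the threshold whose arrays did not overlap between groups, 6 genes named in advance (Prmt5, Myc, Trp53, Mdm2, Mdm4 and Cdkn1a), up to 4 members of each list, and any gene singled out for a closer look. Because the check of row IDs failed, none of those gene and list results, nor the planned set tests, are given here. Rows are compared between arrays without gene names. The values of a row do not depend on the IDs. The choice of the 8367 rows does, and with it their counts and adjusted p-values. In place of the named genes, the 2 rows that rose most and the 2 that fell most among the called rows of the 8367 without overlap between groups are given by deposited ID. This change was made after the data were examined.

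Intensities were corrected for background with neqc of limma 3.58.1 in R 4.3.3, using the detection p-values and an offset of 16, then quantile normalized and taken to log2. Rows with a detection p under 0.05 on at least 4 of the 8 arrays were kept, which left 10970 rows (42.7%). As planned, the brightest row of each symbol was tested, giving 8367 rows. Of the other kept rows, 707 had no single symbol and 1896 were dimmer rows of a symbol. Since the symbols come through the IDs, that choice among rows is close to arbitrary, and the results for all 10970 rows are given as well. OHT and control were compared with lmFit and eBayes of limma without covariates, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Values are means of normalized log2 intensity with the SD over 4 arrays, and fold changes carry the SE of the fit. Background correction enlarges the measured changes of dim rows, and a larger offset makes them smaller, so the sizes of such changes depend on that step. The number of arrays limits the precision.

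Both groups carry the replicate numbers 1 to 4 in the labels, which do not say that the numbers pair the samples. The check of pairing correlated the deviations of samples from their group means over the 10970 rows. Samples with the same number correlated at 0.458 to 0.492, above the limit of 0.1 set for pairing, and 8 of 8 samples lay closest to the sample of their own number in the other group. Samples of another number within the sets 1 and 2 or 3 and 4 correlated at 0.354 to 0.423, and samples across these sets at -0.471 to -0.386, so most of the correlation follows the sets. Within them, the difference between the numbers correlated between OHT and control at 0.123 for numbers 1 and 2 and at 0.109 for numbers 3 and 4. The pairing was read from the values and is weak beyond the sets. Results with the replicate number as a block are given beside the planned fit where they differ from it.

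The fits were tested on simulated arrays built from the row means, the replicate effects and the spread left after these effects. Both samples of a number received the same replicate effect, a stronger pairing than these samples showed. Rows of both sizes were changed in the same arrays. Recovery with the block may therefore be higher in the simulation than in these data. Each replicate effect was the mean of 2 samples and so held part of their spread, which was then added again in full. Recovery without the block may for that reason be lower in the simulation. The same holds for the test between replicates 1 and 2 and replicates 3 and 4. The recovery for OHT against control comes from 1 simulated set of arrays for each choice of rows. In the comparison of OHT with control over 8367 rows, 62 of 100 rows changed by 1 on the log2 scale and 96 of 100 rows changed by 2 were recovered without the block. With the block 100 of 100 were recovered at either size, with 7 false calls among the unchanged rows. Over 10970 rows, 45 of 100 rows changed by 1 and 97 of 100 changed by 2 were recovered without the block. With the block these were 94 and 100 of 100, with 12 false calls, and 1 row was called in arrays simulated with no change. The test of whether the change with OHT differed between replicates 1 and 2 and replicates 3 and 4, with 2 samples in each of its 4 cells, was run on 20 simulated sets. It recovered a median of 0 of 100 rows at a difference of 1 and of 25.5 of 100 at 2, and 0 at 2 in 4 of the 20 sets. Alternatives covered the background correction, normalization, the authors' value table, the filter on dim rows, the choice among the rows of a symbol, the variance model, array weights, the replicate block, the threshold and leaving out each sample.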

Results

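The series measured RNA levels in cultured lineage-negative fetal liver cells of mouse embryos after 24 h with OHT or with ethanol. The series title places the work in a study of MYC, the arginine methyltransferase PRMT5 and the core splicing machinery, and the comparison asks how OHT changed RNA levels in these cells. There were 4 OHT samples and 4 control samples, each on 1 array. Mean intensity was 573 ± 51.0 in OHT and 581 ± 43.2 in control (SD, n = 4 per group), a difference within the spread between arrays (two-sided exact permutation p = 0.857). The number of rows detected was 11218 ± 276 in OHT and 11239 ± 494 in control (SD, n = 4 per group; exact permutation p = 0.943). Adjusted over these 2 tests both p-values were 0.943, and the smallest p that the design allows is 0.0286. Spearman correlations between arrays over all 25695 rows lay between 0.849 and 0.882, so the arrays ranked the rows alike.

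The row IDs did not carry the brightness that their genes would give. Olfactory and vomeronasal receptors are hardly used outside sensory tissue, and ribosomal proteins are among the most abundant transcripts of any growing cell. The 1303 rows with IDs of olfactory and vomeronasal receptors had a median brightness at percentile 52.5 of all rows, with quartiles at 25.5 and 77.9. The 85 rows with IDs of ribosomal proteins had a median at percentile 52.3, with quartiles at 29 and 75. Mean percentiles were 51.2 for receptors and 50.2 for ribosomal proteins, a difference of -1.01 for ribosomal minus receptor rows (two-sided permutation p = 0.763 over rows). By detection, 581 of the 1303 receptor rows (44.6%) and 33 of the 85 ribosomal rows (38.8%) passed the filter. Keratin rows, of an epithelial family, had a median percentile of 45.2, and rows of proteasome subunits, which every cell uses, one of 56.9.

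**Figure D1:**
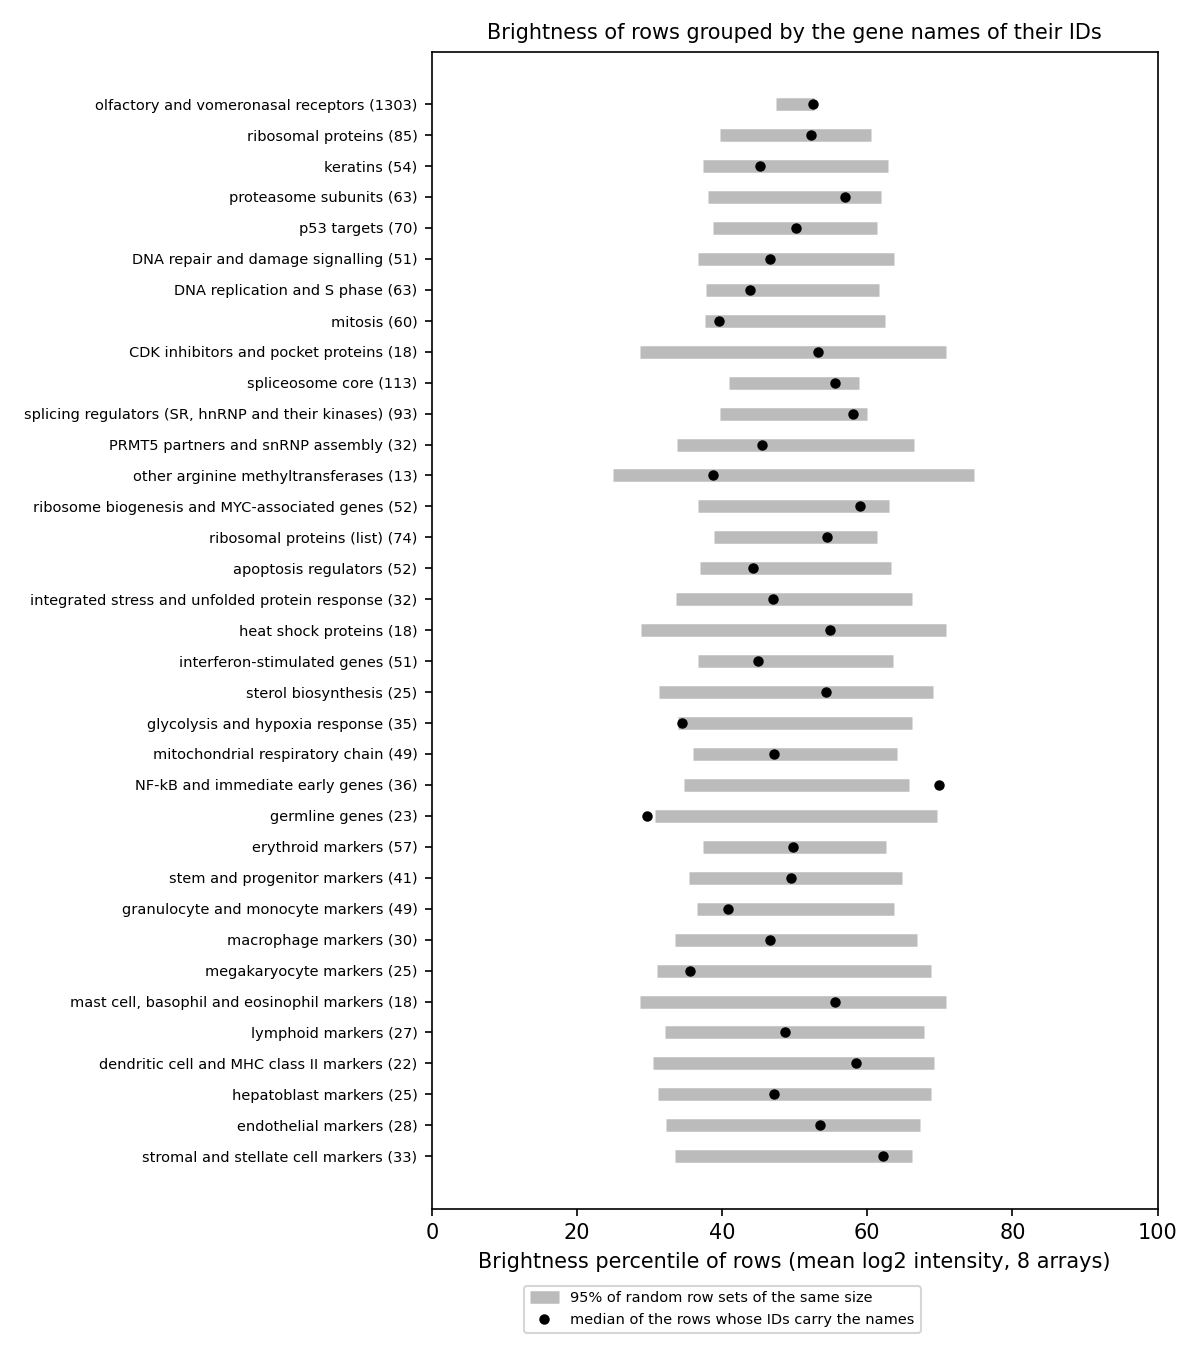
Each point is the median brightness percentile of the rows whose IDs carry the names of a family or list, with the number of rows in brackets, and each grey bar spans 95% of 10000 random row sets of the same size. The horizontal axis is the percentile of mean log2 intensity over the 8 arrays. The points for 29 of 31 lists lie within their bars, as do all 4 families.

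The lists gave the same result. Medians of the 31 lists ran from percentile 29.7 to 69.9, and 2 of the 31 lay outside the range that held 95% of random row sets. The median of the erythroid markers, genes of red cell formation, was at percentile 49.8 against 37.4 to 62.6 for random sets of 57 rows. That of the lymphoid markers was at 48.6 against 32.1 to 67.8. The spliceosome core, made of the proteins of the splicing particles, lay at 55.6 against 41.0 to 58.8. Markers of hepatoblasts lay at 47.2 against 31.2 to 68.8. The lists outside the random range were the NF-kB and immediate early genes at 69.9 and the germline genes at 29.7.

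Rows of the same symbol showed no link either. Among the 994 symbols whose pair of rows did not stand next to each other in the file, brightness of the pair correlated at 0.023 across symbols. In the order of the file, neighbouring rows correlated in brightness at 0.280 when they shared a symbol and at 0.289 when they did not. Levels and changes are therefore reported for rows and not for genes, and no statement is made on Prmt5, splicing factors or any pathway.

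Few rows passed the adjusted threshold between OHT and control. The planned fit leaves the differences between replicate numbers in its spread, so rows that did not pass are not shown to be unchanged. Of 8367 rows tested, 2 were higher and 5 were lower in OHT than in control by limma with Benjamini-Hochberg adjustment. An unadjusted p under 0.05 was found in 754 (9.01%). Of the 5 lower rows, 1 was below detection on all 4 OHT arrays. With its OHT values raised to at least the lowest detected signal of each array, it fell by 0.151 on the log2 scale. With arrays only centred on their medians the split was 2 higher and 3 lower. With the replicate number as a block, 6 rows were higher and 8 lower, and 5 of the 7 rows remained among them. With the block, 1401 rows (16.7%) had an unadjusted p under 0.05 in limma. Of these 748 were higher and 653 lower in OHT, against 311 higher and 443 lower without the block. Over all 10970 rows the counts were 2 higher and 5 lower, with 5 rows shared with the planned fit, and with the block 14 higher and 22 lower. The median SE of a log2 change was 0.190 without the block and 0.144 with it. A change of at least 1 on the log2 scale was measured in 52 of the 8367 rows, 18 of them higher and 34 lower. OHT and control arrays did not overlap in 460 rows (5.5%), of which 166 were higher and 294 lower in OHT. Chance gives 2.86% if the 8 arrays are exchangeable, which the structure of the replicate numbers contradicts. The 7 other splits that part all 4 pairs gave 1.20% to 2.13%. Outside these, replicates 1 and 2 against 3 and 4 gave 17.2%. OHT replicate 1 with control replicates 1, 2 and 3 against the rest gave 5.88%, so 5.5% was not above every split. That last split had 1395 of all kept rows at an unadjusted p under 0.05 in limma, against 956 in the real split. The 7 other splits that part all 4 pairs had 218 to 430 such rows. With the block they had 330 to 709, against 1766 in the real split. These 8 splits, the real one among them, are too few for a share under 0.05. Without the block, the count of called rows changed when single arrays were left out. It ran from 0 to 28 over the 8 fits that left out 1 sample each. It was 0 without control replicate 1, 2 or 3, and 1 without OHT replicate 2 or 3. It was 2 without OHT replicate 1 or control replicate 4, and 28 without OHT replicate 4. Leaving out 1 array makes replicates 1 and 2 against 3 and 4 unequal between the groups. Their difference then enters the comparison, so the changed counts cannot be laid to the left-out array alone. No such fit was run with the block.

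Among the 8367 rows, the largest called change by the fit was in row ILMN_3163302. Its normalized log2 intensity was 5.97 ± 0.69 in OHT and 9.26 ± 0.13 in control (SD, n = 4 per group), a log2 change of -3.29 (SE 0.30, limma adjusted p = 0.00902), with a 95% interval from -3.96 to -2.62 that covers the spread between arrays under this background correction only. Without background correction the change was -1.80 (limma adjusted p = 0.000153) and in the authors' value table -1.79 (0.000155), both outside that interval. It was detected on all 4 control arrays and on 2 of the 4 OHT arrays. It was below detection in OHT replicates 3 and 4. With each OHT value raised to at least the lowest detected signal of its array, it fell by 3.25 on the log2 scale. The rows just before and just after it in the file, which the choice of 1 row per symbol had left out, fell with it over all 10970 rows. The one before was at 7.19 ± 0.26 in control and was detected on 1 of the 4 OHT arrays, so the size of its fall is not given. The one after was detected on all 8 arrays, at 6.02 ± 0.66 in OHT and 9.31 ± 0.23 in control (log2 change -3.29, SE 0.30). Both had a limma adjusted p of 0.00377. The annotation gives both neighbours other symbols than the row between them. Row ILMN_2716212 was at 5.79 ± 0.35 in OHT and 7.54 ± 0.25 in control, a log2 change of -1.75 (SE 0.20, limma adjusted p = 0.0307), against -0.70 without background correction (0.0260) and -0.70 in the authors' value table (0.0261). Row ILMN_3123043 was at 12.40 ± 0.12 in OHT and 10.95 ± 0.34 in control, a 2.72-fold increase (log2 change 1.44, SE 0.18, limma adjusted p = 0.0329). Row ILMN_1233838 was at 14.08 ± 0.29 in OHT and 12.75 ± 0.15 in control, a 2.51-fold increase (log2 change 1.33, SE 0.17, limma adjusted p = 0.0329). With the replicate block the adjusted p-values of these 4 rows were 0.0149, 0.0190, 0.0284 and 0.0190, in the order given. Leaving out 1 sample was again run without the block only. It ended the call of ILMN_3163302 in 3 of 8 fits, those without control replicate 1, 2 or 3 (adjusted p 0.0524 to 0.0714 in limma). It ended that of ILMN_3123043 in 6 of 8 fits (adjusted p up to 0.179), those without replicate 1, 2 or 3 of either group. The calls of ILMN_2716212 (0.0788 to 0.127) and ILMN_1233838 (0.089 to 0.179) ended in 7 of 8 fits, all but the one without OHT replicate 4. The direction held in all 8 fits for each of the 4 rows. Since their groups did not overlap, leaving out a sample could not have changed it.

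**Figure D2:**
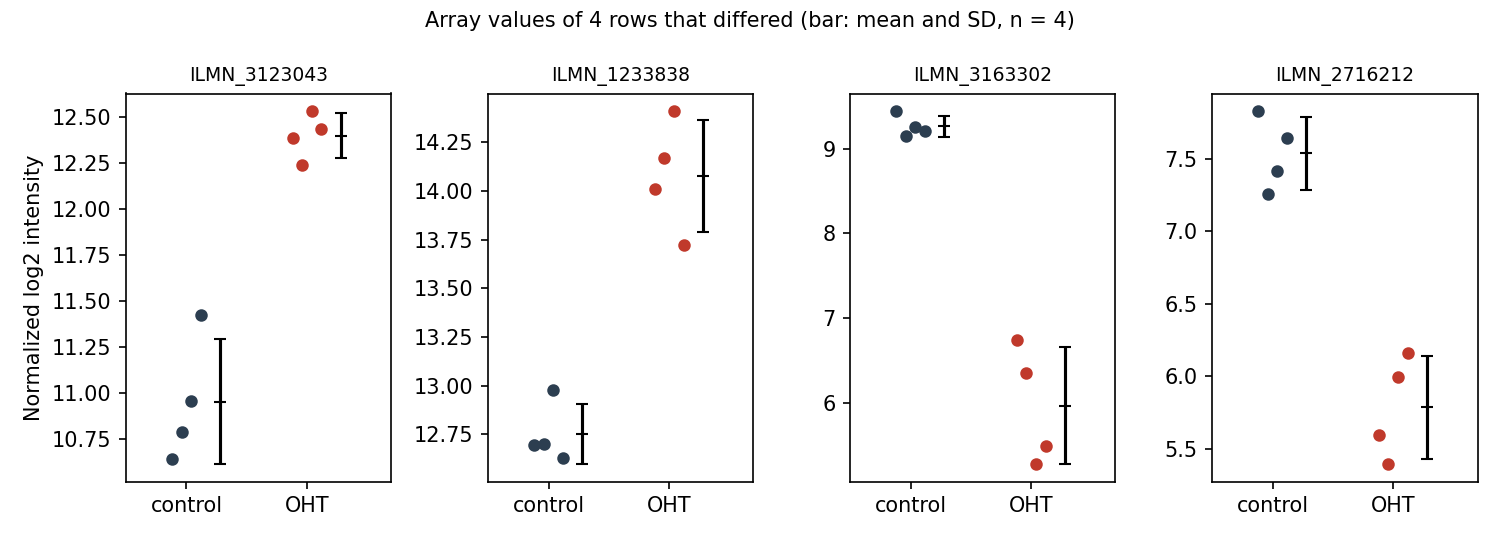
Points are single arrays and bars the mean and SD (n = 4 per group) of normalized log2 intensity for the 4 rows given by ID, each panel with its own vertical axis. In every panel the 4 OHT arrays lie apart from the 4 control arrays, with group means of 12.40 and 10.95 for ILMN_3123043, 14.08 and 12.75 for ILMN_1233838, 5.97 and 9.26 for ILMN_3163302, and 5.79 and 7.54 for ILMN_2716212.

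The largest difference among the arrays was not the treatment. The leading principal component held 43.1% of the variance of the 10970 rows and separated replicates 1 and 2 of both groups from replicates 3 and 4. The next component held 17.8% and separated OHT from control. By sums of squares, 42.4% of the variance lay between replicates 1 and 2 and replicates 3 and 4 (1 degree of freedom). Numbers within those held 18.8% (2 degrees of freedom), OHT against control 16.7% (1), and the rest 22.2% (3). These shares cannot be ranked without their degrees of freedom. Between replicates 1 and 2 and replicates 3 and 4, 938 of 10970 rows (8.55%) passed the threshold, 498 higher and 440 lower in replicates 3 and 4. That count takes the 4 arrays of each side as independent. With the samples of a number averaged, which leaves 2 values on each side, 599 rows passed in limma, 343 higher and 256 lower. This split of the numbers was made after the data were examined and has no counterpart in the labels.

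**Figure D3:**
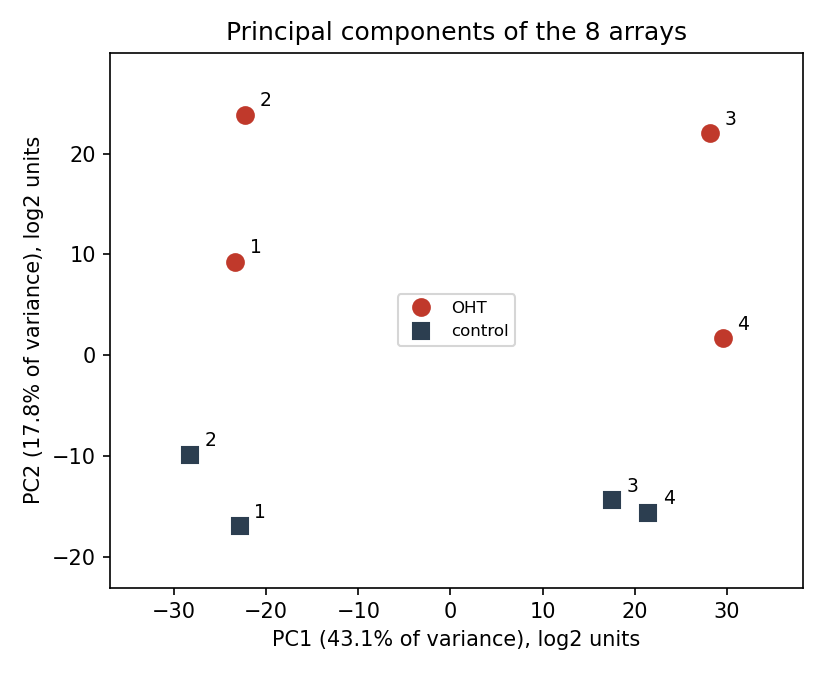
Each point is 1 array, placed by its scores on the leading pair of principal components of 10970 rows, in log2 units, with its replicate number beside it. Replicates 1 and 2 lie between -28.2 and -22.3 on the horizontal axis and replicates 3 and 4 between 17.5 and 29.6. On the vertical axis the OHT arrays lie between 1.66 and 23.9 and the control arrays between -16.9 and -9.86.

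The change with OHT was partly shared between arrays that have no sample in common. The change measured in replicates 1 and 2 and that in replicates 3 and 4 correlated across rows at r = 0.397 (Spearman 0.334, covariance 0.0479 over 10970 rows, which are not independent replicates). The 8 other ways of dividing the arrays within the replicates 1 and 2 and within the replicates 3 and 4 gave r between -0.177 and 0.176. They are too few for a share under 0.05, and some of them keep the real contrast in 1 of the sets. The direction was shared by 61.7% of all rows, by 118 of the 140 rows that moved by at least 1 on the log2 scale in replicates 1 and 2, and by all 42 rows that moved by at least 1 in both. Tested on their own, replicates 1 and 2 gave 0 called rows among 8367 in limma (696 at an unadjusted p under 0.05) and replicates 3 and 4 gave 1 (772 at an unadjusted p under 0.05). The change differed between them by at least 1 on the log2 scale in 199 of 10970 rows. The limma test of this difference called 0 rows. Over 20 simulated sets it recovered 0 to 2 of 100 rows with a difference of 1. With a difference of 2 it recovered 0 to 49 of 100. These recoveries may be low, for the reason given with the simulation. The test does not show that the changes were alike.

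**Figure D4:**
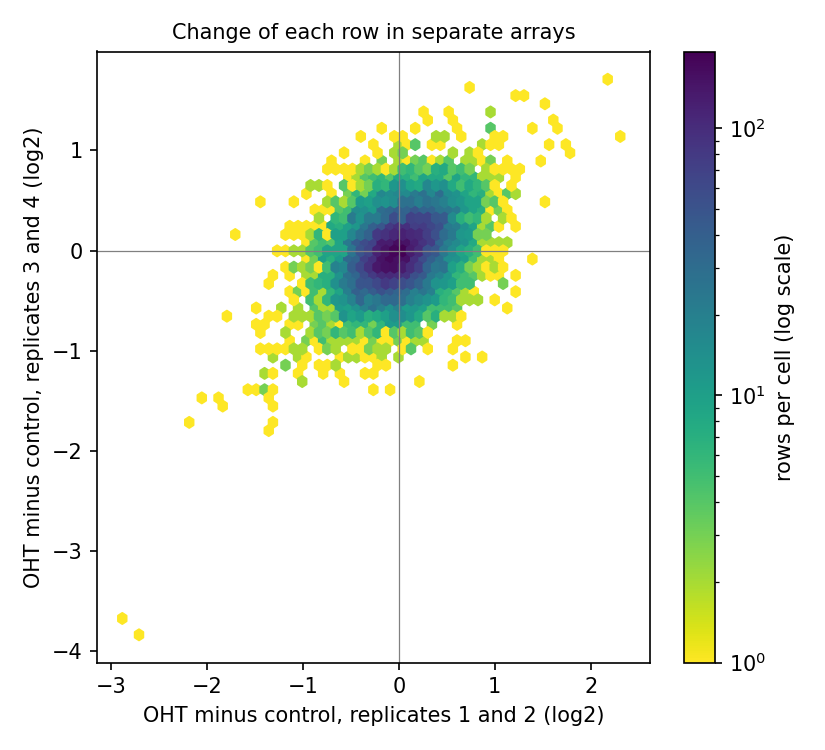
Each hexagonal cell counts rows, on a log colour scale, by their change with OHT in replicates 1 and 2 (horizontal axis) and in replicates 3 and 4 (vertical axis), both as OHT minus control in log2 units. The cloud of 10970 rows is tilted upward to the right (r = 0.397), and the 42 rows that moved by at least 1 in both lie at the lower left and upper right.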

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

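All tests in this part were chosen after the result was seen. Among the control arrays, 1 stood apart in the number of detected rows: replicate 1 had 11973, against 10910 to 11084 on the other 3, a gap of 0.836 of the group's range, which is beyond the 95% limit of Dixon's test for 4 samples. Of 12 groups of reported values tested this was the 1 beyond the limit, and chance passes it in about 1 of 20. Among the 6 groups of the 3 called rows not given by ID, 1 was also beyond the limit, again through control replicate 1. In that row it was at 8.44 on the log2 scale, against 8.03 to 8.09 on the other control arrays. No explanation of this array was tested.

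The difference between replicates 1 and 2 and replicates 3 and 4 was the largest structure of the arrays. Scaling or background correction is argued against as its whole source, since with the samples of a number averaged at least 657 rows still differed under the other normalizations tried, against 599 in the planned one. A sample exchanged between these sets without the other sample of its number is argued against by 8 of 8 samples lying closest to their own number. Both samples of a number moved together would leave that count unchanged, so it does not test such an exchange. An unlabelled batch, such as a hybridisation run, a culture day or a litter, may be the source of the 599 rows, and technical and biological versions of it cannot be told apart because the labels name neither.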

How the results depend on the processing

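The background offset of 50, the term for replicates 1 and 2 against 3 and 4, the fits on either pair of numbers, the block over all kept rows, the averaging of samples of a number and every comparison of replicates 1 and 2 with 3 and 4 were chosen after seeing the data. The other settings were fixed before for the counts. The counts of 2 rows higher and 5 lower in OHT moved by over 1.5 times as follows, and unless stated the cause was not tested. Median centring gave 3 lower, and keeping rows above the median brightness gave 3 lower. Trend and robust variance gave 7 higher and 11 lower. The replicate block gave 6 higher and 8 lower, and over all kept rows 14 higher and 22 lower. The term for replicates 1 and 2 against 3 and 4 gave 8 higher and 8 lower. These last fits take a known difference between arrays out of the spread. An adjusted p under 0.01 gave 0 higher and 1 lower, by the stricter threshold. With fewer samples, replicates 1 and 2 alone gave 0 higher and 0 lower, and replicates 3 and 4 alone 0 higher and 1 lower. Leaving out 1 sample, without the block, gave 0 to 7 higher and 0 to 21 lower. The fits with no call had 521, 624 and 636 rows at an unadjusted p under 0.05 in limma, without control replicates 1, 2 and 3. The 7 called rows kept their direction in every fit that tested them. Since their groups did not overlap, leaving out samples or adding a block could not have changed it.

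Row ILMN_3163302 kept its call in 20 of 24 alternatives (log2 change -3.83, from replicates 3 and 4 alone, where OHT was below detection, to -1.79, adjusted p 0.000153 to 0.132), ILMN_3123043 in 17 of 25 (1.29 to 1.599, 0.00175 to 0.508), ILMN_2716212 in 16 of 25 (-2.05 to -0.70, 0.0112 to 0.508) and ILMN_1233838 in 15 of 25 (1.22 to 1.45, 0.00175 to 0.508). The smallest changes of both falling rows came from leaving out the background correction or from the authors' value table, which has none (-1.80 and -1.79, and -0.70 in both). The correlation of the change between replicates 1 and 2 and replicates 3 and 4 ran from 0.261 with no filter on dim rows to 0.506 with no background correction, over 9 alternatives. The rows that differ between those numbers ran from 725 to 1181, and from 473 to 1049 with the samples of a number averaged. Slide as a block was not run, as no slide is named in the files used here, and alternatives for gene and list results were not run. Signal over background limits dim rows: the median SE over all kept rows was 0.241 in the dimmest of 4 equal brightness classes and 0.156 in the brightest.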

Other observations

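All tests in this part were chosen after the result was seen, apart from the comparison of OHT with control itself. The row IDs and the brightness of their rows do not go together, and a candidate explanation is that the values stand in another order than the IDs. The file order of the values has a structure of its own: neighbours correlated in brightness at 0.285 in file order and at 0.011 once sorted by ID. The longest stretch of dim rows, by a mean over 100 rows below percentile 35, spanned 1266 rows, where 100 shuffles gave none. Olfactory receptor IDs numbered 1143, and whether that stretch holds their values was not tested. The change with OHT follows the file as well, at r = 0.306 between neighbouring rows, 0.292 where their IDs shared a symbol and 0.302 where they did not, against -0.031 to 0.0327 in 100 shuffles and 0.0107 in ID order. Symbols given to the IDs at random are argued against, because 22.6% of neighbouring IDs shared a symbol and shuffled symbols gave at most 0.0224%. A simple alphabetical order of the annotated symbols was not borne out at the exact places it predicts. In the file, 22.7% of all places were as bright as the one that ribosomal proteins would take. For the olfactory receptors, 28.6% were as dim. Those places were scaled from the symbol order, with rows lacking a single symbol spread evenly. An alphabetical order shifted along the file would miss them and stays open. Row ILMN_3163302 and its neighbours on either side, 3 rows in succession called over all kept rows, may thus measure the same transcript, which was not identified. A reordering of the values and an annotation displaced along the IDs cannot be told apart, since either leaves neighbours with the same symbol no more alike than others. Which order the values follow stays open, no biological explanation was tested, and the rows are not renamed here.

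Whether the arrangement of the samples alone gives a count such as the 7 called rows was examined over the 35 ways to split the 8 arrays into groups of 4. As many rows or more were called in 2 of the 35, the real split among them, so chance is not excluded by this count. The other was replicates 1 and 2 against replicates 3 and 4, with 780 rows, which points to a structure of the samples, and the remaining 33 splits called 0. With the replicate number as a block, the real split called 14 rows. Of the 8 splits that part all 4 pairs, 1 called as many, the real one, and the highest of the others was 0, but 8 splits are too few for a share under 0.05. Over all kept rows the real split called 36 with the block and the highest of the others 0.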
